A study of Mus musculus with 16 samples.

How the data were processed

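Primordial germ cells (PGCs) of mouse embryos were profiled by 3′ RNA sequencing in 16 libraries, 8 from floxed Prdm1 embryos at E11.5 and 8 from wild-type embryos at E10.5, E11.5 and E13.5. Per the labels, the floxed cells were sorted by EYFP fluorescence or with an antibody against SSEA-1, and the wild-type cells by Dppa3-EGFP. Complementary DNA was amplified with 11 PCR cycles, and for the wild-type libraries it was made from 1 ng of RNA. Per the submitters' processing notes, reads were trimmed with cutadapt 1.3, mapped to mm10 with TopHat 1.4.1 and counted per gene with Cufflinks 2.2.0. The deposited values are in RPM, a reads-per-million unit relative to gene-assigned reads and not divided by gene length, in a table of 26219 genes with Entrez identifiers. In the wild-type table the authors also listed 92 ERCC spike-in RNAs. All value columns were used.

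Within a library, 99.63% to 99.78% of the positive values were whole multiples of a single step, within 0.05 reads, which places the depth at about 2798000 to 5032000 reads per floxed library and 1485000 to 4783000 per wild-type library. Between 31 and 58 genes per library had fractional values, so the values were analysed as RPM and not as read counts. A library showed 9062 to 10032 genes at 5 RPM or more. The floor of 3 reads corresponded to 0.596 to 2.02 RPM per library. Such floors and the 95% counting intervals cover counting error only, since PCR copies are not independent molecules. The 10 most abundant genes took 5.06% to 6.07% of reads. Gene positions came from a RefSeq annotation of GRCm38/mm10, in which 24619 of the 26219 identifiers were found.

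Values were tested as log2(RPM + 1) with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3. Genes needed at least 5 RPM in 4 floxed or 2 wild-type libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The floxed libraries were compared as CKO-labelled against control. The wild-type libraries were fitted together, with the comparisons E11.5 against E10.5, the mean of both sexes at E13.5 against E11.5, and E13.5 female against male. These comparisons share libraries, so no overlap between them was counted. The labels name nothing that libraries with the same replicate number share, and no block was used. Named genes are Prdm1, the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 RPM whose groups did not overlap, and up to 4 members of each list with the smallest p. Predicted and unnamed genes were skipped, and a few genes picked by this rule are not reported here.

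The comparisons, the tests, the rule for named genes, the alternatives and 26 gene lists were fixed before the data were examined. The lists cover core and early PGC, pluripotency, late germ cell and piRNA, meiosis, male germ cell, mesodermal, S phase, G2 and M phase, kinase inhibitor, p53 and apoptosis, DNA methylation, retinoic acid, imprinted, glycolysis, oxidative phosphorylation, immediate-early and stress, and migration genes, PRDM1 targets known from lymphocytes, sex-linked genes, and markers of gonadal somatic, Sertoli, pre-granulosa, endothelial, erythroid, macrophage and mesonephric cells. Lists with at least 3 tested members were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were run beside it. Each list's genes were also adjusted over the list alone. The 6 sets of genes called in the wild-type comparisons were tested in the floxed libraries in the same way, with Fisher's exact test for overlaps among the genes measured in both tables, a background set after the data were seen.

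The methods were tested on simulated data of the same size, with 1 dispersion for all genes. It was 0.0192 for the floxed libraries and 0.01, the lowest value allowed, for the wild-type libraries. Spread that differs between genes, and libraries that stand apart, were not simulated, so the shares below may not hold for the real data. For the floxed comparison 53.7% of 1.5-fold, 93.9% of 2-fold and 100% of 4-fold changes were called, with 8 of 9249 unchanged genes. For the wild-type comparisons 14.1% to 38.1% of 1.5-fold, 68.8% to 78.1% of 2-fold and 95.4% to 98.4% of 4-fold changes were called. Alternatives covered the pseudocount (0.1 and 10), the filter (none, and 20 RPM), scaling (median-ratio and quantile), the variance model (no trend, array weights), the threshold (adjusted p under 0.1, and 2-fold), a replicate block, the groups in the fit, and each replicate left out. Added after the data were seen were limma voom on reads recovered from the steps, a fit without control 1 and CKO-labelled 4, and a somatic marker covariate. Y-linked genes and the alternative that used them were not analysed here, and the list of sex-linked genes had 1 of 5 genes matched and 0 tested. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.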

Results

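Gene expression was measured by 3′ RNA sequencing in primordial germ cells (PGCs), the embryonic precursors of sperm and eggs, sorted from mouse embryos. The series title concerns the requirement for PRDM1, also called BLIMP1, a transcriptional repressor needed for PGC specification, during later PGC development. The first set held 8 libraries of cells collected at E11.5 (embryonic day) from embryos with floxed Prdm1 alleles, 4 labelled as conditional knockouts (CKO) and 4 as controls. Pregnant females received 3 mg 4-hydroxytamoxifen per 25 g body weight at E10.5, and the CKO-labelled embryos also carried a Dppa3-driven, tamoxifen-inducible Cre transgene that the controls lacked. The other set held 8 libraries of wild-type PGCs carrying a Dppa3-EGFP reporter, with 2 each at E10.5 and E11.5 and 2 each from males and females at E13.5. Values were in reads-per-million units (RPM), relative to the gene-assigned reads of each library. The steps between low values placed the depth at about 2798000 to 5032000 reads per floxed library and 1485000 to 4783000 per wild-type library. The labels do not say whether replicates came from separate embryos or litters, so p-values measure the spread between these samples, which may be technical.

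Prdm1 (Entrez gene 12142, chromosome 10, 44437174 to 44528558, GRCm38/mm10), the targeted gene, was listed at 66.2, 50.7, 63.0 and 73.0 RPM in control libraries 1 to 4. In CKO-labelled libraries 1 to 4 it was listed at 79.9, 84.1, 76.6 and 89.4 RPM. The group means were 63.2 ± 9.33 and 82.5 ± 5.50 RPM (SD, n = 4 each), every CKO-labelled library lying above every control. The log2 fold change of 0.39 ± 0.12 (SE) did not pass the test over all genes (limma, adjusted p = 0.164). Adjusted over the 15 measured core and early PGC genes alone, Prdm1 passed as higher in the CKO-labelled libraries. A 3′ tag can lie outside the part of a gene removed by Cre, and the labels do not name the deleted exons, so this level checks neither the deletion nor the labels. The libraries are therefore called CKO-labelled, and each direction below rests on that label.

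The comparison of CKO-labelled with control libraries asks which transcripts differ in PGCs 1 day after induced Prdm1 deletion. Prps1, which encodes a phosphoribosyl pyrophosphate synthetase used in nucleotide synthesis, rose from 4.04 ± 0.469 to 64.0 ± 13.7 RPM (SD, n = 4 each). Nmi, an interferon-inducible partner of STAT and MYC proteins, rose from 23.6 ± 3.06 to 132 ± 14.6 RPM. Tgif1, a homeobox repressor in TGF-β signalling, rose from 17.1 ± 9.22 to 90.9 ± 11.9 RPM, and Slc7a3, a cationic amino acid transporter, from 12.9 ± 4.11 to 72.0 ± 8.29 RPM. Umodl1 fell from 29.7 ± 7.03 to 9.12 ± 2.18 RPM, and the transcription factor gene Gata2 from 36.4 ± 8.63 to 13.8 ± 4.50 RPM. Sohlh2, a basic helix-loop-helix regulator of germ cell differentiation, fell from 64.2 ± 12.8 to 28.6 ± 5.72 RPM.

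Across 9384 genes tested, 228 were called, of which 181 were higher and 47 lower in the CKO-labelled libraries (limma, Benjamini-Hochberg adjusted p under 0.05). Among these, 122 changed at least 2-fold, 111 of them higher. On the log2(RPM + 1) scale, which understates the change of low genes, the largest rises among called genes with a mean of at least 10 RPM were those of Prps1 (3.67 ± 0.18, SE, adjusted p = 1.89e-07), Tgif1 (2.46 ± 0.26), Slc7a3 (2.44 ± 0.20), Nmi (2.43 ± 0.13) and Vcan (2.35 ± 0.29), the last encoding the matrix proteoglycan versican. Erap1, Tead2, Zfp518b, Dirc2 and Gpr125 followed, with log2 fold changes from 1.97 to 2.27. The largest falls were those of Umodl1 (-1.60 ± 0.21, adjusted p = 0.000737), Gata2 (-1.36 ± 0.23), Vrtn (-1.32 ± 0.16) and Sohlh2 (-1.14 ± 0.18). Calcoco2, Capg, Epha2, Lrrfip1, Ceacam10 and Npnt followed, from -1.01 to -0.89. Prps1 lies at chromosome X, 140456603 to 140476140, Nmi at chromosome 2, 51948498 to 51973489, and Umodl1 at chromosome 17, 30954648 to 31010710 (GRCm38/mm10). The count was 137 without CKO-labelled replicate 2 and 139 with a filter at 20 RPM. Groups differed in the Cre transgene as well as in the intended deletion. The protocols name a sort on EYFP and one on SSEA-1 antibody without tying either to a group.

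**Figure D1:**
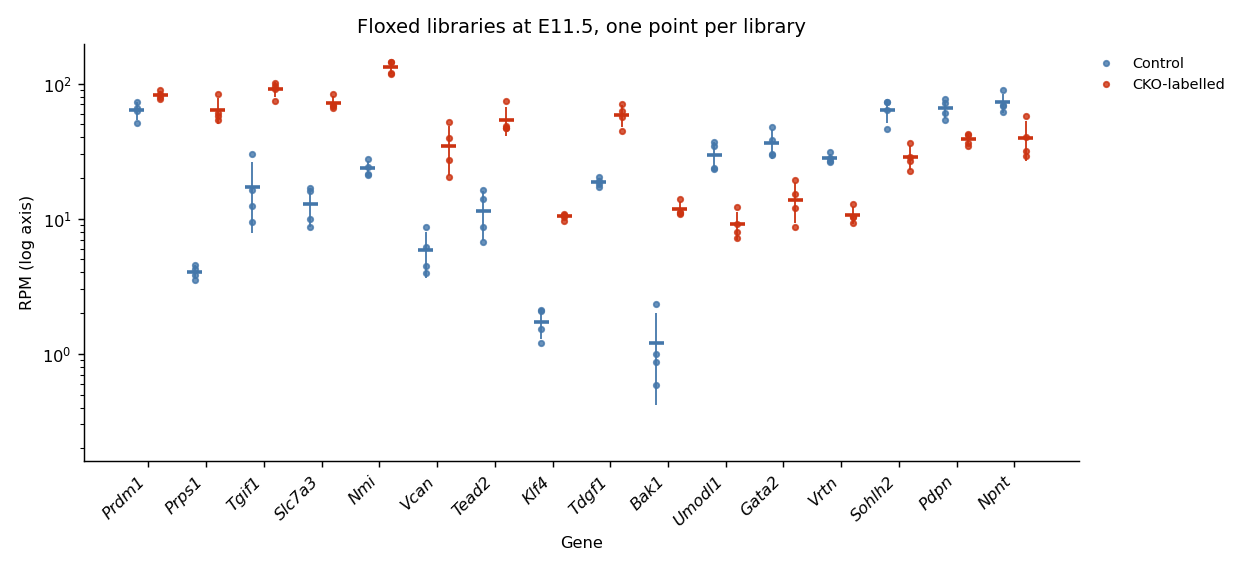
RPM on a log axis for named genes in the 8 floxed libraries at E11.5, with 1 point per library, a bar at the group mean and a line of 1 SD on either side. Prps1 lay between 3.50 and 4.58 RPM in controls and between 53.9 and 84.1 RPM in CKO-labelled libraries, while Prdm1 was not lower in the latter.

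Of 20 testable gene lists, 3 were called in this comparison by camera with a preset correlation, and 0 with an estimated correlation. The late germ cell and piRNA pathway genes were lower as a group (adjusted p = 0.000416, and adjusted p = 0.448 with an estimated correlation). By limma 0 of its 20 measured members were called, over all genes or adjusted over the list alone (5 were lower and 0 higher at an unadjusted p under 0.05). Piwil2, a PIWI protein that binds piRNAs, was at 85.4 ± 18.3 RPM in controls and 58.7 ± 8.11 RPM in CKO-labelled libraries (SD, n = 4 each). The RNA helicase gene Ddx4 was at 279.7 ± 79.9 and 201 ± 44.0 RPM, and neither gene passed the test (adjusted p = 0.155 and 0.353 by limma). Of 20 settings, Piwil2 was called in 1, that without control replicate 3 (adjusted p = 0.0318 by limma), and Ddx4 in 0. The p53 and apoptosis genes were higher as a group (adjusted p = 0.00674, and adjusted p = 0.448 with an estimated correlation). In that list 3 of 19 members rose, also 3 adjusted over the list alone, among them the apoptosis effector gene Bak1 (1.20 to 11.7 RPM) and the BH3-only gene Pmaip1 (3.06 to 16.9 RPM). Cdkn1a, a classical p53 target, was at 17.4 and 17.8 RPM and was not called. The retinoic acid response genes were higher as a group (adjusted p = 0.0122, and adjusted p = 0.448 with an estimated correlation). In it 2 of 4 members rose, also 2 adjusted over the list alone, among them Crabp2, which encodes a retinoic acid carrier (5.07 to 19.6 RPM). The retinoic acid call ended in 7 of 19 settings, those without CKO-labelled replicate 4 (adjusted p = 0.0830), control replicate 1 (adjusted p = 0.0501) or both (adjusted p = 0.211, the largest), with no filter on low values (adjusted p = 0.0623), with array quality weights (adjusted p = 0.0912), with the somatic marker level as a covariate (adjusted p = 0.0574) and with the replicate number as a block (adjusted p = 0.0541). The p53 call ended with no filter on low values (adjusted p = 0.0947) and with a filter at 20 RPM (adjusted p = 0.145). Without 1 library, 5 lists were called when it was CKO-labelled replicate 1, CKO-labelled replicate 3 or control replicate 3.

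The other 17 lists were not called (adjusted p from 0.0646 to 0.893), and 6 different genes in them were. In the list of core and early PGC genes 2 of 15 members fell, and 5 fell with 2 higher adjusted over the list alone. Prdm1 was among the 2 higher, and Prdm14 among the 5 lower. Podoplanin (Pdpn) fell from 65.6 ± 10.2 to 38.7 ± 3.78 RPM and the receptor gene Kit from 248 ± 19.8 to 185 ± 15.8 RPM (SD, n = 4 each). Prdm14, another regulator of PGC specification, was at 72.0 ± 7.07 and 52.5 ± 5.08 RPM without passing the test over all genes (limma, adjusted p = 0.0806). Prdm14 was called lower in 4 of 20 settings (smallest adjusted p = 0.0141 by limma). These were array quality weights, the replicate number as a block, and the fits without control replicate 1 or without it and CKO-labelled replicate 4. The pluripotency factor gene Klf4 rose from 1.73 ± 0.443 to 10.4 ± 0.560 RPM. It was the only called member of the 20 measured pluripotency genes, of which 3 were higher adjusted over the list alone. Of 10 male germ cell genes, 2 rose, with 3 adjusted over the list alone: Tdgf1, a co-receptor for Nodal (18.6 to 58.7 RPM), and the de novo DNA methyltransferase gene Dnmt3a (28.1 to 61.3 RPM). Uhrf1, which recruits the maintenance methyltransferase, rose from 4.48 to 13.2 RPM. It was the 1 called gene of 22 S phase genes and, with Dnmt3a, made 2 of 15 DNA methylation and histone silencing genes, the same counts adjusted over the list alone. Kit was also the 1 called gene of 8 migration and adhesion genes, with 1 higher and 1 lower adjusted over the list alone. The calls of Kit, Uhrf1, Calcoco2, Capg, Epha2, Ceacam10 and Npnt each ended in at least 3 of the alternative settings, always including the one without CKO-labelled replicate 2, where the count of calls was 137 (largest adjusted p = 0.141 for Kit and 0.101 for Uhrf1). Called by limma were 0 of 15 meiosis genes, 4 mesodermal and posterior patterning genes, 4 PRDM1 targets known from lymphocytes, 22 G2 and M phase genes and 4 cyclin-dependent kinase inhibitors. None were called either of 13 imprinted genes, 16 glycolysis genes, 26 oxidative phosphorylation genes, 11 immediate-early and stress genes, 4 endothelial markers and 3 mesonephric epithelium markers. At an unadjusted p under 0.05 there were 1 higher and 2 lower for meiosis genes, 1 higher and 0 lower for mesodermal and posterior patterning genes and 1 higher and 0 lower for imprinted genes. There were 4 higher and 0 lower for glycolysis genes, 0 higher and 1 lower for oxidative phosphorylation genes, 0 higher and 1 lower for immediate-early and stress genes and 0 higher and 1 lower for mesonephric epithelium markers, and 0 for the rest. Adjusted over the list alone, 1 higher and 0 lower passed among mesodermal and posterior patterning genes, 2 higher and 0 lower passed among glycolysis genes and 0 higher and 1 lower passed among mesonephric epithelium markers. The pluripotency genes had a median log2 fold change of -0.09 and a mean of 0.09. Core and early PGC genes were called without CKO-labelled replicate 3 or control replicate 2 (adjusted p = 0.0376 and 0.0376). Imprinted genes were called without CKO-labelled replicate 2 or 3 (adjusted p = 0.00840 and 0.0376), and glycolysis genes in 4 settings, among them those without CKO-labelled replicate 1 or control replicate 3 (adjusted p = 0.0130 and 0.0119). Migration and adhesion genes were called with a filter at 20 RPM (adjusted p = 0.0416), and male germ cell genes without control replicate 1 and CKO-labelled replicate 4 (adjusted p = 0.0432). Mesonephric epithelium markers, lower in CKO-labelled libraries (adjusted p = 0.0646), were called in 10 of 19 settings. These included both other scalings, array quality weights, voom and the somatic covariate (adjusted p from 0.00437 to 0.0473 over the 10). The lists of sex-linked genes and of gonadal somatic, Sertoli, pre-granulosa, erythroid and macrophage markers had under 3 members past the filter and were not tested.

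Transcripts of other gonadal cells differed between the floxed libraries. The summed level of gonadal somatic and mesenchymal markers was 354 RPM in CKO-labelled library 4 and 126 RPM in library 1, against 22.7 and 13.8 RPM in libraries 2 and 3 and 15.0 to 82.4 RPM in controls. Endothelial markers summed to 157 RPM in CKO-labelled library 4 and to 38.0 to 58.5 RPM in the other 7. Crabp2, a called retinoic acid gene, was at 20.4 RPM in CKO-labelled library 4, 30.0 RPM in library 1, 12.7 RPM in library 2 and 15.5 RPM in library 3. The imprinted gene Igf2, which mesenchyme also expresses, was at 88.3 RPM in CKO-labelled library 4 and 8.35 RPM in library 2. Control library 1 and CKO-labelled library 4 correlated least with their own groups, at a mean r across genes of 0.965 and 0.964. In alternatives chosen after the data were seen, 211 genes were called without these libraries (157 higher, 54 lower) and 173 with the somatic marker level as a covariate (142 higher, 31 lower).

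**Figure D2:**
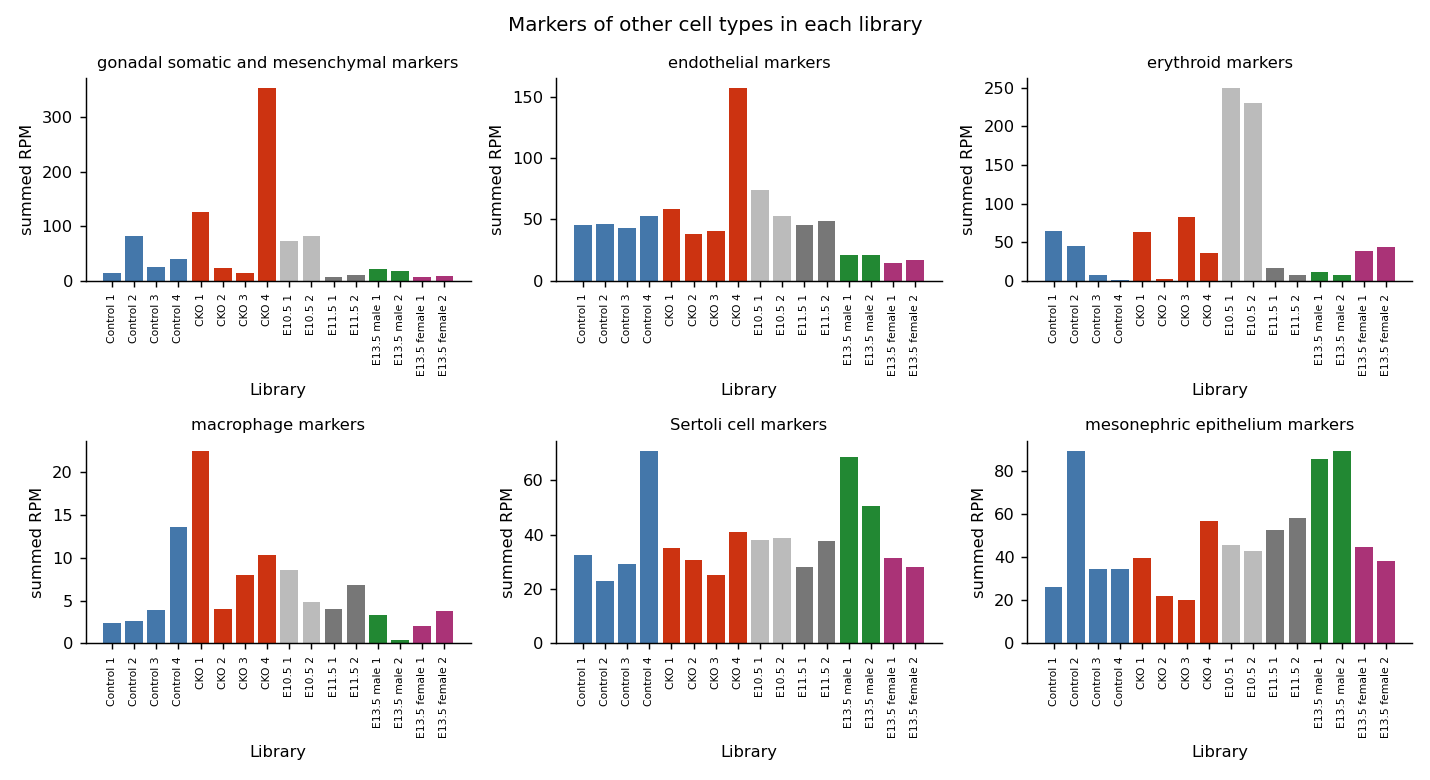
Summed RPM of fixed marker lists of 6 other cell types (linear axes starting at 0), with 1 bar per library coloured by group. Gonadal somatic and mesenchymal markers stood at 354 RPM in CKO-labelled library 4, and erythroid markers at 249.6 and 231 RPM in the E10.5 libraries.

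The genes that changed in wild-type development were next examined in the floxed libraries, to ask whether CKO-labelled PGCs resembled earlier or later cells. Of 6 sets of genes called higher or lower in the wild-type comparisons, 0 were called by camera (smallest adjusted p = 0.252 with the preset and 0.910 with an estimated correlation) and 0 by fry (0.991). Of the genes called in the floxed libraries, 161 of the 181 higher and 47 of the 47 lower were measured in the wild type too. The 47 lower in CKO-labelled libraries included 19 of the genes lower and 5 of those higher at E13.5 than at E11.5, against 9.77 and 12.7 from independent lists (Fisher's exact test over 9303 genes, two-sided, Benjamini-Hochberg adjusted p = 0.0229 and 0.0332 over 12 overlaps). The 161 higher ones included 42 of the genes lower in E13.5 females than in males, against 27.5 (adjusted p = 0.0244 by the same exact test). They included 50 of the genes higher and 46 of those lower at E13.5, against 43.5 and 33.5 (adjusted p = 0.295 and 0.0549). This background was set after the data were seen. Over all genes tested in the floxed libraries, used first, only the overlap lower in both passed (adjusted p = 0.0211 by the exact test). The overlaps of lower genes with those higher at E13.5, and of higher genes with those lower in females, then each had adjusted p = 0.0706. Fisher's exact test treats all genes as equally likely to be called, whatever their level, so it does not separate abundance from a shared direction. Across the 9303 genes the log2 fold changes of the CKO-labelled comparison were hardly related to those of the wild type. Pearson's r was -0.091 for E11.5 against E10.5, 0.040 for E13.5 against E11.5 and -0.035 for female against male. The 2 sets of libraries shared no samples, but were normalised separately. Without CKO-labelled replicate 2, 2 sets were called, the genes higher at E11.5 than at E10.5 being lower (adjusted p = 0.0118) and those lower at E11.5 being higher (adjusted p = 0.0401). The former set was also called without control replicate 3 (adjusted p = 0.0228) and with no filter on low values (adjusted p = 0.0245).

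From E10.5 to E11.5, when PGCs settle in the genital ridges, germ cell genes rose in wild-type cells. Dazl, an RNA-binding regulator of germ cell commitment (chromosome 17, 50279393 to 50293620), rose from 34.2 ± 1.83 to 240.0 ± 27.3 RPM (SD, n = 2 each). Mael, which acts in transposon silencing, rose from 17.2 ± 3.28 to 49.7 ± 5.46 RPM. The E-box factor gene Tcfl5 rose from 1.32 ± 0.0521 to 12.9 ± 1.75 RPM. The embryonic globin genes Hba-x and Hbb-y fell from 72.3 ± 7.77 to 2.25 ± 1.58 RPM and from 101 ± 5.91 to 3.83 RPM. The imprinted gene Mest fell from 86.7 ± 12.8 to 22.1 ± 1.09 RPM, and the lactate dehydrogenase gene Ldha from 282 ± 19.7 to 101 ± 2.40 RPM. Prdm1 was at 81.2 ± 1.91 RPM at E10.5 and 61.9 ± 6.68 RPM at E11.5 and was not called (limma, log2 fold change -0.39 ± 0.16, SE, adjusted p = 0.157).

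Of 10749 genes tested, 460 were called, 248 higher and 212 lower at E11.5 (limma, adjusted p under 0.05), and 162 of these changed at least 2-fold (76 higher, 86 lower). The majority turned to lower with median-ratio scaling (217 higher, 287 lower), without E11.5 replicate 1 (204 higher, 282 lower) and in 5 other settings. Among called genes with a mean of at least 10 RPM over the 8 libraries, the largest rises were those of Dazl (2.77 ± 0.10, SE, adjusted p = 3.17e-18), Tcfl5 (2.58 ± 0.24), Trim47 and the testis-expressed gene Tex101 (2.15 ± 0.31), with Tuba3a, Usp26, A2ld1, Adad2 and Grtp1 among those at 1.85 or more. Tuba3a has a near-identical copy, Tuba3b, so its reads are uncertain. Among named genes with that mean, the largest falls after the globins and Mest were those of Tpm4, Grb10, Pxdn, Setdb2, Aldh1a2, Ccnd1 and H19, at -1.90 to -1.63. The count was 105 without E10.5 replicate 1, 167 without E10.5 replicate 2, 80 with no filter on low values, 27 without the mean-variance trend and 279 with array quality weights. The settings were followed for 50 called genes, a part of those that the rule for named genes picked. Of these, 14 were called under every setting, among them Dazl, Tcfl5, Mael, Mest, Igf2, Ldha, Col3a1, Hba-x and Hbb-y.

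Of 23 testable lists, 10 were called, 3 higher and 7 lower at E11.5, of which 3 held with an estimated correlation. Late germ cell and piRNA genes rose as a group, with 14 of 23 members called higher and 16 adjusted over the list alone (camera adjusted p = 2.27e-22, and adjusted p = 0.0393 with an estimated correlation). They included Dazl, Mael, Ddx4 (69.4 to 166 RPM) and Slc25a31 (22.4 to 62.4 RPM). Imprinted genes fell as a group, with 7 of 17 called lower and 9 adjusted over the list alone (adjusted p = 6.29e-10, and adjusted p = 0.0393 with an estimated correlation). Phlda2 went from 353 to 163 RPM, Igf2 from 84.7 to 27.1 RPM and H19 from 86.4 to 27.5 RPM. Erythroid markers fell with them, 5 of 6 called lower and 6 adjusted over the list alone (adjusted p = 1.81e-15, and adjusted p = 0.0393 with an estimated correlation). Their sum was 249.6 and 231 RPM at E10.5 and 16.8 and 6.83 RPM at E11.5, and Hba-a1 may share reads with its copy Hba-a2. Gonadal somatic and mesenchymal markers also fell, 3 of 4 called lower and 4 adjusted over the list alone (adjusted p = 6.75e-07, and adjusted p = 0.0956 with an estimated correlation). They summed to 73.1 and 82.3 RPM at E10.5 and to 6.73 and 9.96 RPM at E11.5. The collagen gene Col3a1 went from 29.7 to 0.764 RPM.

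The remaining calls at E11.5 rested on fewer members. Migration and adhesion genes were lower, with 1 of 12 called and 1 higher and 7 lower adjusted over the list alone (adjusted p = 0.000791, and adjusted p = 0.0956 with an estimated correlation). Retinoic acid response genes were lower, with 2 of 6 called and 2 adjusted over the list alone, among them the retinaldehyde dehydrogenase gene Aldh1a2 (adjusted p = 0.00726, and adjusted p = 0.157 with an estimated correlation). The p53 and apoptosis genes were higher, with Ccng1 the 1 of 19 called and 2 adjusted over the list alone (adjusted p = 0.00137, and adjusted p = 0.105 with an estimated correlation). Meiosis genes were higher, with 4 of 25 called and 4 adjusted over the list alone, among them the cohesin gene Stag3 (52.6 to 88.2 RPM) and Hormad1 (15.4 to 30.9 RPM; adjusted p = 0.0470, and adjusted p = 0.157 with an estimated correlation). S phase genes were lower, with 2 of 22 called and 3 adjusted over the list alone, Pcna and Mcm4 (adjusted p = 0.0410, and adjusted p = 0.157 with an estimated correlation). Glycolysis genes were lower, with 3 of 18 called lower and Gpi1 higher, and 4 lower and 2 higher adjusted over the list alone (adjusted p = 0.0410, and adjusted p = 0.186 with an estimated correlation). The meiosis, S phase and glycolysis calls ended in 7, 5 and 7 settings (largest adjusted p = 0.232, 0.142 and 0.136). The meiosis call ended without E11.5 replicate 2 (adjusted p = 0.223) or E10.5 replicate 2 (adjusted p = 0.0866). The S phase call ended without E11.5 replicate 1, E11.5 replicate 2 or E10.5 replicate 2 (adjusted p = 0.0598, 0.0932 and 0.0943), and the glycolysis call without any 1 of the 4 libraries (adjusted p from 0.0568 to 0.0932). The other 13 lists were not called (adjusted p from 0.0641 to 0.990), and 17 different genes in them were. Among these were Ifitm3 (924 to 504 RPM), a surface marker of early PGCs, and the Nodal antagonist genes Lefty1 and Lefty2, which share sequence and may share reads (17.5 to 44.9 and 28.6 to 76.1 RPM). In these lists the genes called higher and lower were 0 and 1 of 15 core and early PGC genes, 2 and 1 of 20 pluripotency genes, 4 and 1 of 16 male germ cell genes and 1 and 1 of 8 mesodermal and posterior patterning genes. They were 0 and 1 of 22 G2 and M phase genes, 0 and 1 of 5 cyclin-dependent kinase inhibitors, 0 and 2 of 14 immediate-early and stress genes and 2 and 0 of 4 mesonephric epithelium markers. Among 4 PRDM1 targets known from lymphocytes, 17 DNA methylation and histone silencing genes, 26 oxidative phosphorylation genes, 3 Sertoli cell markers and 5 endothelial markers, 0 were called by limma, with 2, 4, 4, 0 and 0 at an unadjusted p under 0.05, respectively. Adjusted over the list alone, the counts differed for pluripotency genes (4 higher, 4 lower), PRDM1 targets known from lymphocytes (1 higher, 1 lower), G2 and M phase genes (0 higher, 2 lower) and DNA methylation and histone silencing genes (1 higher, 3 lower). They also differed for immediate-early and stress genes (2 higher, 2 lower). Oxidative phosphorylation genes were called higher in 5 of 15 settings, among them that without E10.5 replicate 2 (adjusted p = 0.0458), and male germ cell genes in 4 (smallest adjusted p = 0.00314). Core and early PGC genes were called lower in 2 settings, and mesodermal genes and endothelial markers with no filter (smallest adjusted p = 0.0277, 0.00491 and 0.00310). The calls of Pcna, Mcm4 and Gpi1 ended without either E10.5 replicate, those of Hormad1, Ccng1 and Lefty1 without E10.5 replicate 1 and that of Aldh1a2 without E10.5 replicate 2 (largest adjusted p over all settings from 0.0805 to 0.281).

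From E11.5 to E13.5, averaged over both sexes, meiotic genes rose while pluripotency and glycolysis genes fell. Sycp1, a component of the synaptonemal complex, went from 2.72 ± 0.987 RPM at E11.5 to 47.7 ± 8.64 RPM in males and 120.2 ± 30.1 RPM in females (SD, n = 2 each). Dazl went from 240.0 ± 27.3 RPM to 1355 ± 50.3 and 1648 ± 10.6 RPM, and the tudor gene Tdrd7 from 2.67 ± 1.87 RPM to 38.7 ± 9.94 and 64.7 ± 0.426 RPM. The pluripotency gene Klf2 went from 83.2 ± 4.18 RPM to 21.1 ± 0.548 RPM in males and 20.4 ± 6.01 RPM in females, and the glycolytic enzyme gene Hk1 from 66.4 ± 1.32 RPM to 8.87 ± 2.09 and 13.2 ± 0.499 RPM. The kinase gene Lck (chromosome 4, 129548344 to 129573641) went from 52.7 ± 6.46 RPM to 1.71 ± 0.421 and 3.55 ± 1.18 RPM. Prdm1 was at 61.9 ± 6.68, 62.0 ± 4.47 and 48.4 ± 0.183 RPM and was not called (limma, adjusted p = 0.307).

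Of 10749 genes, 5146 were called, 3121 higher and 2025 lower at E13.5 (limma, adjusted p under 0.05), and 1940 changed at least 2-fold (1261 higher, 679 lower). The median log2 fold change of all genes was 0.11, against 0.011 with median-ratio scaling and -0.0073 with quantile normalization. The calls then split into 2606 higher and 2514 lower, and 2555 higher and 2560 lower. The called named genes that were followed through the settings kept their calls and directions under both scalings, and camera compares each list with the other genes. Stra8, the retinoic acid-induced gate to meiosis, had 0 reads at E11.5 and 1.21 and 407 RPM in males and females. Hesx1 likewise had 0 reads at E11.5 and 119 and 0.660 RPM. Taf7l and Mxd4 rested on 1 and 3 reads at E11.5, and their reads pooled over the 4 E13.5 libraries of both sexes gave ratios of 168 (95% counting interval 30.0 to 6655) and 59.9 (20.4 to 291). Other large rises among genes with a mean of at least 10 RPM were those of Sp5, a Wnt target (4.45 ± 0.34, SE), Sycp1 (4.38 ± 0.29), Bnc2, Tdrd7, Zfp238 and Cited1 (3.68 to 4.08). The largest falls were those of Lck (-3.95 ± 0.27, adjusted p = 2.31e-12), the metallothionein genes Mt2 (-3.38 ± 0.12) and Mt1 (-3.37 ± 0.21), and Tmsb4x (-3.37 ± 0.18), followed by Ildr1, Lgals9, Hist1h2bc, Stat4, Serpinb9b and Hmgn5 (-3.20 to -2.96). Hist1h2bc belongs to a family of near-identical histone genes, so its reads are uncertain.

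Of 23 lists, 7 were called, and 3 of them held with an estimated correlation. Meiosis genes rose, with 24 of 25 members called higher and 25 adjusted over the list alone (camera adjusted p = 1.25e-12, and adjusted p = 0.0221 with an estimated correlation). Sycp3 went from 9.18 RPM to 38.2 and 127 RPM, and the meiotic cohesin gene Smc1b from 37.0 RPM to 130.2 and 420.0 RPM in males and females. Late germ cell and piRNA genes rose, with 19 of 23 higher and 1 lower, the same counts adjusted over the list alone (adjusted p = 3.19e-11, and adjusted p = 0.0732 with an estimated correlation). Pluripotency genes fell, with 14 of 20 lower and 1 higher, and 15 and 1 adjusted over the list alone (adjusted p = 9.35e-09, and adjusted p = 0.0221 with an estimated correlation). Among them, Esrrb went from 217 RPM to 103 and 91.3 RPM and Pou5f1 from 748 RPM to 528 and 375 RPM. Glycolysis genes fell, with 15 of 18 lower and 1 higher, and 16 and 1 adjusted over the list alone (adjusted p = 3.31e-11, and adjusted p = 0.0221 with an estimated correlation). Gapdh went from 2409 RPM to 1332 and 969 RPM. Core and early PGC genes fell, with 11 of 15 lower and 1 higher in both counts (adjusted p = 5.62e-06, and adjusted p = 0.0848 with an estimated correlation). They included Ifitm3 (504 RPM to 164 and 140.1 RPM). S phase genes were lower, with 11 of 22 lower and 3 higher, and 12 and 4 adjusted over the list alone (adjusted p = 0.00369, and adjusted p = 0.0848 with an estimated correlation). Endothelial markers were lower, with 3 of 5 called in both counts, Tek at 6.68 RPM before and 1.19 and 0.137 RPM after (adjusted p = 0.0345, and adjusted p = 0.450 with an estimated correlation). That call ended without E13.5 female replicate 1 (adjusted p = 0.0519) or E11.5 replicate 2 (adjusted p = 0.0687), with median-ratio scaling (adjusted p = 0.0675) and with only the compared groups in the fit (adjusted p = 0.0772). The other 16 lists were not called (adjusted p from 0.204 to 0.873), and 98 different genes in them were. The imprinted cell cycle inhibitor gene Cdkn1c went from 10.9 RPM to 38.4 and 61.1 RPM, and the receptor gene Ret from 0.764 RPM to 23.9 and 9.27 RPM. In these lists the genes called higher and lower were 7 and 4 of 16 male germ cell genes, 3 and 2 of 8 mesodermal and posterior patterning genes, 1 and 1 of 4 PRDM1 targets known from lymphocytes and 6 and 6 of 22 G2 and M phase genes. They were 3 and 0 of 5 cyclin-dependent kinase inhibitors, 4 and 4 of 19 p53 and apoptosis genes, 7 and 3 of 17 DNA methylation and histone silencing genes and 4 and 2 of 6 retinoic acid response genes. They came to 5 and 7 of 17 imprinted genes, 8 and 3 of 26 oxidative phosphorylation genes, 2 and 3 of 14 immediate-early and stress genes and 6 and 3 of 12 migration and adhesion genes. For the rest they were 2 and 0 of 3 Sertoli cell markers, 2 and 0 of 6 erythroid markers and 0 and 2 of 4 mesonephric epithelium markers. Among 4 gonadal somatic and mesenchymal markers, 0 were called by limma, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, the counts differed for G2 and M phase genes (7 higher, 6 lower), DNA methylation and histone silencing genes (7 higher, 4 lower) and imprinted genes (5 higher, 8 lower).

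**Figure D3:**
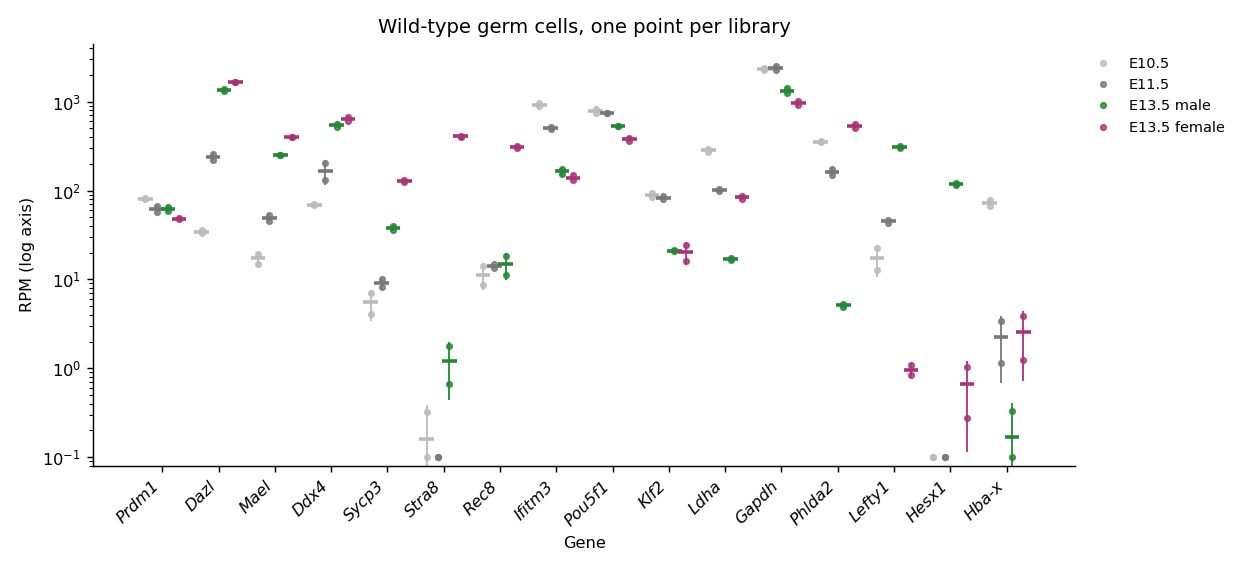
RPM on a log axis for named genes in the 8 wild-type libraries, with 1 point per library, a bar at the group mean and a line of 1 SD on either side. Libraries at 0 are drawn at the bottom of the axis. Dazl stood at 34.2 RPM at E10.5 and 1648 RPM in E13.5 females, and Stra8 stood at 407 RPM in E13.5 females and 1.21 RPM in males.

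At E13.5, when female germ cells enter meiosis, the sexes differed in meiosis genes and male germ cell genes. Stra8 (chromosome 6, 34920163 to 34939344) was at 1.21 ± 0.773 RPM in males and 407 ± 6.64 RPM in females (SD, n = 2 each), and the meiotic cohesin gene Rec8 at 14.8 ± 4.92 and 308 ± 13.6 RPM. The transcription factor genes Gata2 and Id1, the latter BMP-responsive, were at 2.54 ± 1.60 and 5.81 ± 0.752 RPM in males and 283 ± 7.71 and 201 RPM in females. Lefty1 (chromosome 1, 180935022 to 180938401) was at 309.9 ± 8.94 RPM in males and 0.966 ± 0.184 RPM in females, and the homeobox gene Hesx1 at 119 ± 5.00 and 0.660 ± 0.545 RPM. The imprinted gene Phlda2 was at 5.14 ± 0.292 RPM in males and 533 ± 35.3 RPM in females. Prdm1 was at 62.0 ± 4.47 and 48.4 ± 0.183 RPM and was not called over all genes (limma, log2 fold change -0.35 ± 0.16, SE, adjusted p = 0.0803). Adjusted over the core and early PGC genes alone, it passed as lower in females.

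Of 10749 genes, 4038 were called, 2280 higher and 1758 lower in females (limma, adjusted p under 0.05), and 1844 differed at least 2-fold (1184 higher, 660 lower). Quantile normalization gave 2082 higher and 2109 lower. The count was 2708 to 3015 without 1 replicate. Among genes with a mean of at least 10 RPM, the largest differences toward females were those of Stra8 (7.57 ± 0.43, SE, adjusted p = 3.47e-14), Phlda2 (6.44 ± 0.13), Gata2 (6.40 ± 0.24), Msx2 (5.46 ± 0.23), Id1 (4.89 ± 0.23), Dsp (4.42 ± 0.22) and Rec8 (4.32 ± 0.24). Sct and Slc22a18 rested on 1 read each in males, with ratios of 381 (95% counting interval 68.0 to 15058) and 241 (43.1 to 9565). Msx1as overlaps Msx1 on the other strand, and the sources used here do not say that counting used the strand, so its reads cannot be told from those of Msx1. The largest differences toward males were those of Lefty1 (-7.31 ± 0.25, adjusted p = 2.33e-19), Lefty2 (-6.91 ± 0.24), Hesx1 (-6.22 ± 0.47) and Pmaip1 (-5.67 ± 0.43), and among those that followed were Cthrc1, Enpp2, Etv1 and Notch3. Tdgf1 had 0 reads in females and 17.2 RPM in males, 48.2-fold above a floor of 3 reads over the group. The 95% counting interval of its male to female ratio began at 38.5.

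Of 23 lists, 9 were called, 7 toward females and 2 toward males, and 2 held with an estimated correlation. Meiosis genes were higher in females, with 19 of 25 called and 21 adjusted over the list alone (camera adjusted p = 5.14e-08, and adjusted p = 0.0469 with an estimated correlation). Male germ cell genes were lower in females, with 10 of 16 called, and 12 lower and 1 higher adjusted over the list alone (adjusted p = 3.95e-07, and adjusted p = 0.0469 with an estimated correlation). PRDM1 targets known from lymphocytes were higher in females, with 3 of 4 called in both counts, with adjusted p = 0.000914, and adjusted p = 0.134 with an estimated correlation. They included the HLH inhibitor genes Id3 (49.0 RPM in males and 286 RPM in females) and Id2 (3.11 and 34.0 RPM). Pluripotency genes were lower in females, with 8 of 20 lower and 4 higher in both counts (adjusted p = 0.0152, and adjusted p = 0.175 with an estimated correlation). Lower ones were Dppa5a (2332 and 927 RPM in males and females) and Utf1 (862 and 376 RPM). Mesodermal and posterior patterning genes were higher in females, with 6 of 8 higher and 1 lower in both counts (adjusted p = 0.0226, and adjusted p = 0.260 with an estimated correlation). Retinoic acid response genes were higher, with 4 of 6 higher and 2 lower in both counts, Crabp1 being higher in females and Aldh1a1 higher in males (adjusted p = 0.0312, and adjusted p = 0.261 with an estimated correlation). Imprinted genes were higher, with 8 of 17 higher and 3 lower, and 9 and 3 adjusted over the list alone (adjusted p = 0.0312, and adjusted p = 0.261 with an estimated correlation). They included Igf2 (3.58 RPM in males and 78.0 RPM in females), and Mest in the other direction (143 and 26.2 RPM). Migration and adhesion genes were higher, with 7 of 12 higher and 2 lower, and 8 and 2 adjusted over the list alone (adjusted p = 0.0336, and adjusted p = 0.261 with an estimated correlation). Erythroid markers were higher, with 3 of 6 in both counts, their sum being 39.1 and 43.9 RPM in females and 11.0 and 8.10 RPM in males (adjusted p = 0.0336, and adjusted p = 0.312 with an estimated correlation). That call ended without female replicate 2 (adjusted p = 0.0735). Apart from meiosis and male germ cell genes, each of these calls ended in at least 1 alternative setting. The largest adjusted p was 0.116 for PRDM1 targets, 0.0687 for pluripotency, 0.492 for mesodermal, 0.120 for retinoic acid, 0.108 for imprinted, 0.120 for migration and 0.140 for erythroid genes. The other 14 lists were not called (adjusted p from 0.0572 to 0.858), and 90 different genes in them were. Among these were Dppa3 (6283 RPM in males and 2478 RPM in females) and Tfap2c (30.0 and 107 RPM). In these lists the genes called higher and lower were 6 and 6 of 15 core and early PGC genes, 9 and 1 of 23 late germ cell and piRNA genes, 5 and 0 of 22 S phase genes and 5 and 9 of 22 G2 and M phase genes. They were 2 and 1 of 5 cyclin-dependent kinase inhibitors, 1 and 5 of 19 p53 and apoptosis genes, 2 and 4 of 17 DNA methylation and histone silencing genes and 3 and 8 of 18 glycolysis genes. They came to 8 and 4 of 26 oxidative phosphorylation genes, 2 and 4 of 14 immediate-early and stress genes, 0 and 2 of 3 Sertoli cell markers and 0 and 1 of 5 endothelial markers. For the rest they were 1 and 1 of 4 mesonephric epithelium markers. Among 4 gonadal somatic and mesenchymal markers, 0 were called by limma, with 0 at an unadjusted p under 0.05. Adjusted over the list alone, the counts differed for core and early PGC genes (6 higher, 8 lower), late germ cell and piRNA genes (10 higher, 1 lower), S phase genes (4 higher, 0 lower) and G2 and M phase genes (7 higher, 9 lower). They also differed for cyclin-dependent kinase inhibitors (2 higher, 2 lower), DNA methylation and histone silencing genes (3 higher, 4 lower), glycolysis genes (4 higher, 9 lower) and oxidative phosphorylation genes (9 higher, 5 lower). Glycolysis genes were called lower in 3 of 15 settings, among them those without female replicate 1 or male replicate 2 (adjusted p = 0.0331 and 0.0412). Late germ cell genes were called higher in 5 of 15, S phase genes higher with quantile normalization and Sertoli cell markers lower in 4 of 14 (smallest adjusted p = 0.0228, 0.0368 and 0.0122). The Sertoli cell marker list summed to 68.5 and 50.7 RPM in males and 31.6 and 28.0 RPM in females.

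**Figure D4:**
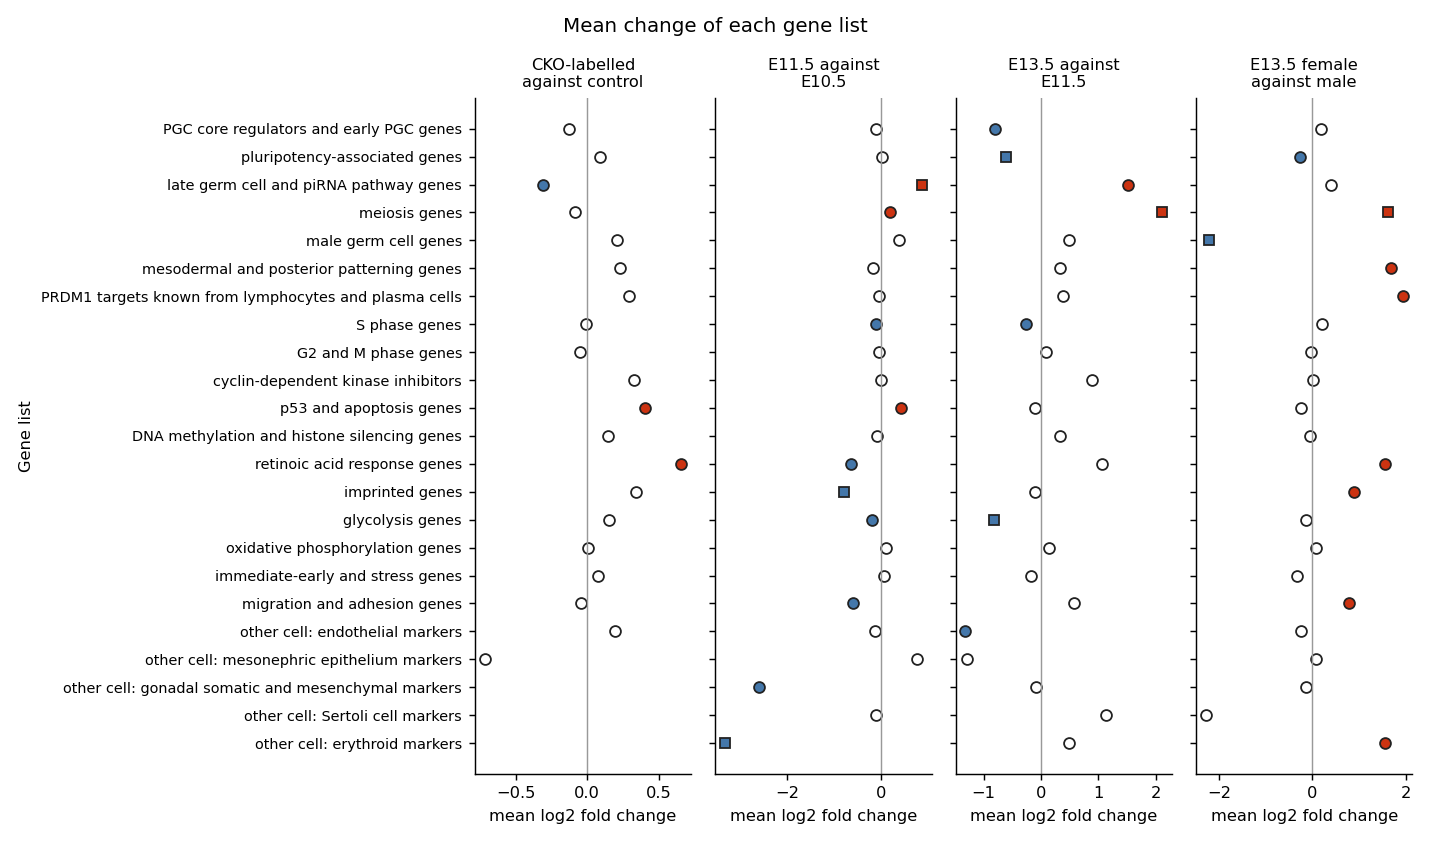
Mean log2 fold change of each testable gene list (horizontal axis, its scale differing between panels) in the 4 comparisons, with 1 symbol per list. Filled symbols were called by camera with the preset correlation (red higher, blue lower), squares also with an estimated correlation, and open symbols were not called; 0 lists were squares in the CKO-labelled comparison and 3 in that of E13.5 with E11.5.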

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

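The tests for swapped labels and for counted reads outside the deleted part of Prdm1, the fit without 2 libraries and the somatic covariate were chosen after the results were seen. For each group of 4 floxed libraries, 116 sets of values were checked for a library far from the others (by its gap to the nearest over the range), and 8 stood apart, where chance gives about 1 in 20.

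Slc7a3 was at 84.3 RPM in CKO-labelled library 1 and at 66.1 to 68.9 RPM in the others of its group. In CKO-labelled library 4, Tead2 was at 74.3 RPM against 47.1 to 48.2 RPM, Zfp518b at 39.0 RPM against 26.0 to 27.6 RPM, Bak1 at 13.9 RPM against 10.9 to 11.1 RPM, and Sycp3 at 24.7 RPM against 36.5 to 38.4 RPM. Prdm14 was at 61.5 RPM in control library 1 and at 74.0 to 76.4 RPM in the other controls. Macrophage markers summed to 13.7 RPM in control library 4 against 2.35 to 3.94 RPM, and mesonephric epithelium markers to 89.3 RPM in control library 2 against 26.2 to 34.6 RPM.

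Of the 46 named genes followed for the change from E11.5 to E13.5, 29 changed by different amounts in the sexes (limma, adjusted p under 0.05 for female against male). Among them 0 were called in opposite directions, which the rule for named genes largely fixed in advance. The largest changes needed every E13.5 library of both sexes on the same side of the E11.5 libraries. List members were picked on the mean of both sexes, in which opposite changes cancel. The female minus male difference (log2) was 7.57 for Stra8 and -6.22 for Hesx1, which had 0 reads at E11.5 and were near the floor of 3 reads at E13.5 in males (Stra8) and in females (Hesx1), where no rise is shown. Of genes higher at E13.5 in both sexes, the rise was larger in females by 3.00 for Cited1, 2.11 for Taf7l, 1.72 for Sycp3, 1.69 for Smc1b, 1.61 for Mxd4, 1.305 for Sycp1, 0.98 for Zfp238, 0.67 for Mael, 0.65 for Cdkn1c and 0.28 for Dazl. The female minus male difference was -2.90 for Bnc2, -1.28 for Ret and -0.57 for Cenpf, which rose more in males. Of genes lower in both sexes, the fall was larger in males by 2.54 for Tmsb4x, 2.01 for Mt2, 1.83 for Tfap2c, 1.81 for Serpinb9b, 1.28 for Mt1, 1.020 for Rrm2, 0.94 for Hmgn5, 0.66 for Hist1h2bc and 0.53 for Cdt1. The female minus male difference was -1.20 for Eno1, -0.73 for Aurkb, -0.49 for Pou5f1, -0.47 for Morc1 and -0.46 for Gapdh, which fell more in females.

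ERCC spike-in reads, which entered no comparison, came to a mean of 1.57% beside the mouse gene reads in the wild-type libraries (1.10% to 1.93%). Of 34 spike-ins above the filter, limma called 8 higher at E11.5 than at E10.5 (median log2 fold change 0.42), 14 lower at E13.5 than at E11.5 (-0.34), and 9 lower in E13.5 females than in males (-0.38). Their share depends on the mouse RNA in each sample, and no call on genes used them.

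The 228 genes called in the CKO-labelled comparison were the most of any of the 35 splits of the 8 libraries into 2 groups of 4. Only 1 split reached that number, and the highest of the others gave 0. A share of 1 in 35 is the smallest that these splits can give, so it argues against chance without excluding it. The other splits mix the groups, so a real group difference would widen their spread and lower their counts. For the number of gene lists called the splits do not argue against chance, since 14 of 35 splits gave at least the 3 lists called and the highest other gave 7. The p-value of each of these 3 lists was not compared across the splits. For the developmental sets 0 were called, a number that all 35 splits must reach (the highest other gave 5), so the splits say nothing about chance there.

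More called genes were higher than lower in the CKO-labelled libraries (181 against 47). Scaling between libraries does not account for this, since 81.2% of calls were higher with quantile normalization. RNA from gonadal somatic cells does not either as a whole. With the somatic covariate, the median log2 fold change of the genes called higher was 0.974 times as large. Libraries that stand apart do not account for it as a whole, with 74.4% of calls higher without them. With array quality weights, the share higher was 69.0% (220 against 99). The intended Prdm1 deletion stays open, as do the Cre transgene, which only the CKO-labelled embryos carried, and a difference in sorting gate; the design does not separate them.

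Prdm1 itself was higher in all 4 CKO-labelled libraries than in any control. A wrongly labelled single library or a swapped pair is argued against, since 0 libraries correlated better with the other group than with their own; an exchange of the whole groups would leave that count at 0 and stays open. Counted 3′ reads lying outside the deleted part could account for a level that did not fall, and the ratio of 1.304 between the group means cannot tell this from an undeleted gene, because the deleted part is not named. No table here shows that PRDM1 protein or full-length transcript was lost.

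At E11.5, imprinted genes were lower than at E10.5 together with erythroid and mesenchymal markers. If RNA from mesenchymal cells carried the imprinted transcripts at E10.5, the slopes of these genes on the mesenchymal marker level in the floxed libraries should predict the fall, and they predicted 31.9% of the summed fall of 474 RPM (24.2% to 32.5% with 1 library left out). If mesenchymal cells at E10.5 resembled those in the floxed libraries, these values argue against them as the whole source of the summed fall. No value here tests that assumption. By gene, 0.566% was predicted for Phlda2 (a fall of 190 RPM), 25.7% for Peg3, 28.9% for Igf2, 32.6% for H19, 68.9% for Grb10, 80.0% for Mest and 326% for Cdkn1c, and in a sum without Phlda2, chosen after this was seen, 52.8% (38.0% to 53.8% with 1 library left out), which leaves these cells open there. RNA from erythroid cells and a change in the germ cells between these days were not tested, and the slopes assume that mesenchymal cells at E10.5 resemble those in the floxed libraries.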

How the results depend on the processing

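Limma voom, the fit without control 1 and CKO-labelled 4, and the somatic covariate were chosen after seeing the data. No called list and 0 of the named called genes reversed, while some lists that were not called changed sign. The majority of calls turned to lower at E11.5 in 7 settings: median-ratio scaling (217 higher, 287 lower), no filter (39, 41), no trend (11, 16), without E11.5 replicate 1 (204, 282), only the compared groups in the fit (194, 214), voom (265, 286) and 2-fold (76, 86). With quantile normalization it turned at E13.5 against E11.5 (2555, 2560) and in female against male (2082, 2109). The settings were followed for a part of the genes picked by the rule for named genes. Of those called, 24 of 31 stayed called under every setting in the CKO-labelled comparison and 14 of 50 at E11.5 against E10.5. In the other wild-type comparisons 45 of 45 and 43 of 43 did.

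For the 228 genes called in the CKO-labelled comparison, the count was 139 with a filter at 20 RPM (fewer genes tested), 122 with the 2-fold requirement, 152 with no filter and 137 to 204 without 1 replicate. Array weights gave 319, voom 228, the fit without 2 libraries 211 and the covariate 173. Its 3 lists became 5 with quantile normalization, 0 with an estimated correlation and 2 to 5 without 1 replicate. Fry called 0 of the 3 (adjusted p = 0.248 for late germ cell, 0.0609 for p53 and retinoic acid genes) and 1 other, DNA methylation and histone silencing genes (higher, adjusted p = 0.0291). Of the developmental sets, 1 was called with no filter and 0 to 2 without 1 replicate. With sets of 200 genes, 0 sets were called by camera, and Fisher's exact test gave adjusted p = 0.00566 for genes lower in both the CKO-labelled libraries and at E13.5, and 0.0249 to 0.0348 for all 4 overlaps with the sex sets. Over all genes tested in the floxed libraries, the background used first, 1 of the 12 overlaps of the full sets passed (lower in both, adjusted p = 0.0211). With sets of 200 genes over that background, genes higher in CKO-labelled libraries and lower in females did not pass (Fisher's exact test, adjusted p = 0.0624). The other overlaps with the sex sets each had adjusted p = 0.0397 by that test, and the overlap lower in both had 0.00541. For the 460 genes at E11.5 against E10.5 the count was 80 with no filter, 27 without the trend, 279 with array weights, 162 with 2-fold, 901 at an adjusted p under 0.1, 551 with voom and 105 to 486 without 1 replicate, and its 10 lists became 3 with an estimated correlation. For E13.5 against E11.5, 1940 of 5146 genes passed 2-fold, 4149 to 4667 were called without 1 replicate, and the 7 lists became 3 with an estimated correlation and 14 with fry. For female against male, 1844 of 4038 genes passed 2-fold, 2708 to 3015 were called without 1 replicate, and the 9 lists became 2 with an estimated correlation and 14 with fry. Except for the 2-fold requirement, fewer genes and fewer samples, the cause was not tested.

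Replicate numbers were not taken as pairs. Same-number floxed libraries correlated across genes at 0.241, 0.0198, 0.252 and 0.182, and those with different numbers at -0.229 to 0.183. Libraries numbered 1, 3 and 4 each correlated best with the one of their own number. Control 2 correlated best with CKO-labelled 3, and CKO-labelled 2 with control 3. The values lean toward a batch shared by number, which is neither shown nor excluded and which the main fit left out. With the numbers as a block, 314, 559, 5167 and 4099 genes, 2, 10, 7 and 9 lists and 0 developmental sets were called. Leaving out a wild-type replicate leaves 1 in its group, assumed to vary like the other groups. Prdm1 was called lower in females with quantile normalization and array weights (smallest adjusted p = 0.0421). The alternative with a Y-linked covariate was not run. Depth limits genes under about 2.02 RPM, the floor of 3 reads in the shallowest library.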

Other observations

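The interferon list and its test were chosen after the called genes were seen. Genes known to respond to interferon stood among the calls in the CKO-labelled libraries, beside Nmi and Erap1. Oasl2, an oligoadenylate synthetase-like gene, rose from 0.978 to 9.28 RPM (log2 fold change 2.42, limma adjusted p = 0.00299), and Parp14 from 3.21 to 14.4 RPM (1.91, adjusted p = 0.000921). Parp9 and its partner Dtx3l rose from 15.8 to 32.6 RPM and from 8.03 to 17.9 RPM, and the cytidine deaminase gene Apobec3 from 1.90 to 9.41 RPM. The immunoproteasome gene Psmb10 rose from 7.30 to 17.3 RPM and the proteasome activator gene Psme2 from 272 to 389 RPM.

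A hypothesis is that interferon response genes rise as a group in the CKO-labelled libraries. A list of 56 such genes was written, of which 22 were tested, 9 were called higher and 0 lower. Since the list was written after those 9 were seen, a test on all members would be circular. A camera test was run on the 13 that were not called (p = 0.796, 32 of 35 splits in an exact permutation of the libraries giving a p as small). It decides nothing either, because leaving out the called members removes those that rose, and the hypothesis stays open. Of the members not called, Stat2 was at 6.17 and 8.31 RPM in control and CKO-labelled libraries, Irf1 at 78.8 and 79.0 RPM, Bst2 at 46.5 and 37.6 RPM and Ddx58 at 23.0 and 20.9 RPM. In the wild-type libraries 20 of the 56 were tested: 0 were called at E11.5 against E10.5 by limma (5 at an unadjusted p under 0.05), 2 were higher and 8 lower at E13.5 than at E11.5, and 2 were higher and 10 lower in females than in males.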
